A study of Mus musculus with 2 samples.

How the data were processed

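ATAC-seq peak lists from 2 libraries were analysed, each made from pooled forebrain of mouse embryos at 15.5 days (78 and 62 embryos), which the labels call biological replicates 1 and 2 of 1 tissue and stage. Per the labels, coordinates are on mm10. The authors deposited 12 peak lists in narrowPeak format: for each replicate alone and for both replicates together, lists of ranked peaks from the irreproducible discovery rate (IDR) procedure, lists kept by an IDR threshold, and lists kept because a peak was found in both pseudoreplicates or in both replicates. The shared lists were derived from the alignments of both replicates, per the labels of the peak lists. The aligner, the peak caller, their versions and the read filters are not given in the sources used here. The same labels say that the IDR-thresholded lists were filtered with a further submitters' file, which was not used here.

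Each deposited list gives, per summit, a score from 0 to 1000, in which higher is better. The smallest score in the deposited IDR-thresholded lists was 540, the value that an IDR of 0.05 takes on this scale. The signal per summit is the enrichment the authors' peak caller gave, relative to a background that the sources used here do not define. It was used to describe, rank or filter regions within a list, for the correlation between the replicates, and for the ratio of X to autosomal promoters within each replicate. The deposited lists also give −log10 p and −log10 q per summit, of which −log10 p served for the left-out regions and for the X chromosome only. No read counts or totals were used, so the depth of each library is unknown.

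A row of a list is a summit, and several summits share an interval. Distinct intervals were taken as regions, and a region's signal is that of its strongest summit. The word peak in the planned design was read as region for overlaps, promoters, distal counts and clusters, and as summit for genomic location and motifs. The conservative list (IDR-thresholded, between true replicates) was the main list. Overlap between replicates needed at least 1 bp, and was set against 100 random circular shifts of the regions within chromosomes (permutation, one-sided). Spearman and Pearson correlations were computed on log2 signal over regions that overlap 1 to 1.

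Genes came from GENCODE release M21 (basic set, assembly GRCm38.p6, whose chromosomes are those of mm10), with 21851 protein-coding genes. A promoter was the sequence within 1 kb of any annotated TSS of a gene. A summit's location was promoter, then exon, then intron, then intergenic. Distal regions lay more than 1 kb from every TSS and were assigned to the nearest protein-coding TSS. The 25 gene lists with 363 members, all of which were found in the annotation, were written from general knowledge. Shares of accessible promoters were tested with Fisher's exact test (two-sided) against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. They were also set against 10000 random lists matched on the decile of the promoter's observed to expected CpG ratio. That ratio was taken at the gene's 5'-most protein-coding TSS only, and the number of TSSs per gene was not matched. Median distal regions per gene were set against 10000 random lists matched on the decile of the interval between neighbouring TSSs (permutation, two-sided). Genes are not replicates, so these tests describe the 2 libraries.

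For motifs, 30 consensus strings were searched on both strands in the 100 bp around each summit and in 100 bp that start 400 bp away on a random side, and compared by the exact McNemar test, distal and promoter summits apart. A flank may lie near another summit of the same region. Several summits can share a region, so summits are not independent, and the p-values of the motif tests may be too small. Distal and promoter summits were compared by Fisher's exact test. Clusters joined distal regions at most 10 kb apart. For the closing section, region sequences were aligned with BLAST+ 2.17.0 to the mitochondrial genome (at least 80% identity over 50 bp), and summit windows to the whole genome (at least 95% identity over 90% of the window). The whole genome included the mitochondrial genome, so a copy elsewhere can be the mitochondrial sequence itself. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

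Lists, motifs, tests, alternatives and the rule for named genes were chosen before the data were examined, except where the closing section says otherwise. The rule named, of each list, up to 4 members with the strongest promoter region, up to 4 with the most distal regions and up to 4 without a promoter region in alphabetical order. It also named the 25 genes with the most distal regions, the genes nearest the 10 strongest distal regions, the 10 largest clusters and the 5 strongest regions specific to each replicate. The strongest distal region of 6 genes was chosen for its sequence after their values were seen, as was the Sox2 map. Alternatives covered the replicated list, the regions above the median signal, each replicate's own IDR-thresholded list, promoter windows of 500 and 2500 bp, other motif windows and backgrounds, other joining distances and other definitions of sharing. Each list was also read per replicate, and values per replicate are given as mean and SD over n = 2. Rows on unplaced scaffolds were left out of gene, motif and location results.

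The tests were checked on simulated data. For the promoter lists, on 21851 genes, 100 of 100 lists planted near 0% were recovered and 3 of 400 unchanged lists were called (0.75%). For the matched distal lists, 25 of 25 lists with 4 regions added per gene were recovered and 0 of 100 unchanged lists were called. For motifs, on 20000 simulated summits, 3 of 3 planted motifs were recovered and 0 of 27 others called. The simulations were simpler than the data. Simulated summits and flanks had the same even base composition and shared no regions. No promoter list was planted at a high share, and distal counts followed interval length. False calls from base composition or from summits that share a region were therefore not checked.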

Results

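Open chromatin was mapped in the forebrain of mouse embryos at 15.5 days of gestation with ATAC-seq, in which a transposase cuts and tags DNA that is not covered by nucleosomes, so that regions with many tags mark accessible regulatory DNA. Tissue came from the B6NCrl strain with both sexes mixed. The series holds 1 group of 2 biological replicates, a pool of 78 embryos for replicate 1 and a pool of 62 embryos for replicate 2, and so allows no comparison between groups. The questions it allows are which genes and regions were accessible, which sequence motifs lay at them, and how far the replicates shared them. The measurements are positions of accessible regions in the mm10 genome, in 12 lists that differ in how strictly peaks were kept. Read totals were not among the values used here, so the depth of each library is unknown and no counting interval is given. The list used throughout, called conservative here, holds peaks that were reproducible between both replicates. It has 91037 summits in 33574 distinct regions with a median width of 995 bp, which cover 34.0 Mb. The lists made from each replicate alone with the same score threshold hold 22436 regions in replicate 1 and 24632 in replicate 2. Each was made within 1 library and is smaller than the conservative list. A call that changes in them may thus reflect how the list was built as well as the library. The signal printed for a region is the authors' own enrichment value.

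Genes of forebrain progenitors and of neurons had accessible promoters. All 18 radial glia genes (the list of neural stem cells of the ventricular zone), all 11 intermediate progenitor genes and 18 of 20 genes of cortical excitatory neurons had a conservative region within 1 kb of a transcription start site (TSS). So did 17 of 18 pan-neuronal genes and all 15 genes of synaptic maturation, against 12721 of all 21851 protein-coding genes, or 58.2%. Foxg1, the transcription factor that patterns the telencephalon, had a promoter region at 12:49383251-49384680 with a signal of 10.1, and 10.4 and 9.77 in the lists of replicates 1 and 2. The promoter of Sox2, the stem cell factor, lay in a region at 3:34649204-34650565 (signal 8.36). The most intense promoter of the pan-neuronal list belonged to Syt1, the calcium sensor of synaptic vesicles, at 10:109010300-109011839 (signal 18.3).

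In Fisher's exact tests (two-sided, Benjamini-Hochberg over 25 lists), the share of accessible promoters was higher than among all other genes for radial glia (adjusted p = 0.00134), intermediate progenitors (0.00926), cortical excitatory neurons (0.00785), pan-neuronal (0.00374), synaptic maturation (0.00172) and forebrain regional genes (0.0337). Genes are not replicates, so these tests describe these 2 libraries. Within the replicates' own lists, the share was 80.6 ± 3.93% for radial glia genes, 77.3 ± 6.43% for intermediate progenitor genes, 87.5 ± 3.54% for cortical excitatory neuron genes and 90 ± 4.71% for synaptic genes (SD, n = 2). In replicate 2 alone the radial glia share was 77.8% (exact test, adjusted p = 0.0856), the intermediate progenitor share 81.8% (0.150) and the forebrain regional share 83.3% (0.102). In replicate 1 alone, intermediate progenitors (72.7%, exact test, adjusted p = 0.271) and forebrain regional genes (75.0%, 0.188) did not pass either.

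Accessibility of promoters followed their CpG content. In 5 equal groups of genes, from the lowest to the highest ratio of observed to expected CpG, 4.30%, 23.2%, 75.1%, 91.9% and 96.6% had a promoter region. The ratio was taken at a gene's 5'-most protein-coding TSS, whereas a region at any TSS counted, so matching on it can miss the accessible promoter. For Nrxn1 it was taken at 17:91093071 and the strongest region lay at 17:90088049-90089031. For Scn2a these were 2:65620771 and 2:65667665-65669165. Against random gene lists matched on that ratio, pan-neuronal genes (94.4% against a mean of 68.3%, permutation adjusted p = 0.0075) and synaptic genes (100% against 62.8%, adjusted p = 0.001, from the smallest p that 10000 lists can give) remained higher. In the same permutation test, radial glia genes (100% against 83.7%, adjusted p = 0.0728), intermediate progenitors (84.3% expected, 0.217), cortical excitatory neurons (74.8% expected, 0.131) and forebrain regional genes (85.7% expected, 0.995) no longer passed. Many promoter regions of these lists lay below the median signal of the conservative list. Among regions above it, 33.3% of forebrain regional, 27.3% of intermediate progenitor, 40.0% of cortical neuron and 44.4% of pan-neuronal genes had one, against 46.0% of all genes. Radial glia (50%) and synaptic genes (53.3%) were closer to all genes than before, and none of these 6 lists passed (exact adjusted p from 0.320 to 1). The forebrain regional call also ended in the replicated list described below (91.7%, exact adjusted p = 0.105) and with promoter windows of 500 bp (83.3%, 0.117) and 2500 bp (91.7%, 0.0511).

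Within the lists, the members differed in signal. Of the radial glia genes, the promoter of Id4, an inhibitor of basic helix-loop-helix factors, was the most intense (13:48260460-48262179, signal 11.3), followed by Vim, an intermediate filament gene (8.75), Sox2 and Pax6, a regulator of cortical progenitors (7.85). Among intermediate progenitor genes, Elavl4, an RNA-binding protein of young neurons (9.65), Btg2, which restrains division (8.45), and Hes6 (8.18) led. The proneural genes Neurog1 and Neurog2 had signals of 5.55 and 4.51. Cortical neuron genes were led by Rorb, a layer 4 transcription factor gene (19:19110888-19112063, signal 11.5), Zfpm2 (10.6) and Pou3f2 (9.39). Slc17a6 and Slc17a7, which encode the vesicular glutamate transporters, had no promoter region. Synaptic genes included the sodium channel gene Scn2a (13.5), the scaffold gene Homer1 (12) and the GABA receptor gene Gabra1 (9.05), and pan-neuronal genes Nrxn1 (14.6) and Syn1 (12.7). Rbfox3, a gene of mature neurons, had none.

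Cell cycle and housekeeping genes were accessible at 14 of 15 and 15 of 15 promoters (Fisher's exact test, adjusted p = 0.0136 and 0.00172). The mitotic checkpoint gene Bub1 (17.4), the cyclin gene Ccnb1 (16.3), the replication genes Mcm3 (15.8) and Pcna (15.5), and the housekeeping gene Hprt (14.3) had some of the highest promoter signals of any list. Given their CpG ratio, 90.3% and 83.4% of such genes were expected to be accessible, and neither list passed that comparison (permutation, adjusted p = 1 and 0.130).

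None of the 39 Hox genes, which pattern the hindbrain, spinal cord and trunk, had a conservative promoter region (Fisher's exact test, adjusted p = 3.948e-14), and neither replicate's own list held one. The exact test and the random lists below take genes as independent. Neighbouring Hox genes may share their state, so their p-values may be too small. Of 12 midbrain and hindbrain regulators, 3 had one (exact adjusted p = 0.0522), namely Egr2 (5.71), Atoh1 (5.69) and En2 (4.89), and En1, Pax2, Pax3 and Barhl1 were among those with none. In either replicate's own list the share was 16.7%, which passed (exact adjusted p = 0.0246 in replicate 1 and 0.0299 in replicate 2). Of 11 diencephalon and hypothalamus genes, 4 had one (exact adjusted p = 0.289), including the transcription factor genes Sim1 (11.4) and Tcf7l2 (7.65), and Dbx1, Foxb1, Nkx2-4 and Olig3 had none. Replicate 1 alone gave 18.2% (exact adjusted p = 0.0415) and replicate 2 alone 27.3%.

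Relative to random lists of the same CpG content, those 3 lists fell further below: 0% against 75.2% for Hox genes, 25% against 83.0% for midbrain and hindbrain genes, and 36.4% against 88.8% for diencephalon genes (permutation, adjusted p = 0.001 for each, from the smallest p that 10000 lists can give). The longer list of peaks found in both replicates without the reproducibility threshold is called replicated here and holds 80770 regions. In it, 25.6% of Hox, 75.0% of midbrain and hindbrain and 72.7% of diencephalon genes had a promoter region. For the last 2 gene lists the low shares thus held in the IDR-thresholded lists and not in this longer one. The exact test on the replicated list gave an adjusted p of 2.27e-05 for Hox genes, 0.704 for midbrain and hindbrain genes and 0.860 for diencephalon genes.

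Genes of the subpallium, the ventral forebrain that makes GABAergic neurons, were split. A promoter region was present at 14 of 22 genes (Fisher's exact test, adjusted p = 0.798; 59.1% in either replicate's own list), led by Ebf1 (9.71), Sp9 (9.57), Arx (9.52) and Isl1 (8.35), and Gsx1, Gsx2, Lhx6 and Lhx8 had none. The share of 63.6% lay below the 85.6% of CpG-matched lists (permutation, adjusted p = 0.0471), but in the replicated list 95.5% of these genes had a promoter region, above other genes (exact test, adjusted p = 0.00605).

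Of the other cell types that a forebrain dissection holds, microglia and endothelial genes had lower shares of accessible promoters. Of 13 microglia and macrophage genes, only C1qc, a complement gene, had a promoter region (signal 5.87; exact adjusted p = 0.00172), and neither replicate's own list held one. Of 13 endothelial genes, 3 had one, Erg (6.6), Kdr (5.97) and Slco1c1 (4.38; exact adjusted p = 0.0337), and the adherens junction gene Cdh5 had none. Replicate 1 alone gave 7.69% and replicate 2 alone 15.4% of endothelial genes, with Kdr and Slco1c1 in neither. The shares for oligodendrocyte lineage (6 of 12), astrocyte (6 of 10), pericyte and meninges (7 of 13), choroid plexus and ependyma (5 of 10), erythroid (3 of 11) and neural crest genes (5 of 10) did not differ from other genes (exact adjusted p from 0.0857 to 1). The oligodendrocyte lineage share of 50% was 25% in replicate 1 alone and 33.3% in replicate 2 alone. In the replicates' own, smaller lists, 3 more lists passed the threshold as lower shares. These were erythroid genes with 9.09% in either replicate's list (exact adjusted p = 0.0112 and 0.00833), and, in replicate 1 only, pericyte and meninges genes with 15.4% and choroid plexus genes with 10.0% (exact adjusted p = 0.0157 for both, with 30.8% and 20% in replicate 2). Among the members with a promoter region were Olig2 (8.46) and Pdgfra (7.53) of the oligodendrocyte lineage, Glul (10.9) of astrocytes and Foxj1 (8.72) of ciliated ependyma. Mog, Mag, Gfap and Aqp4 were among those with none. Whether early and mature glial genes differ was not tested. The endothelial call ended in the replicated list (53.8%, exact adjusted p = 0.704) and with a promoter window of 2500 bp (30.8%, 0.0632). Among regions above the median signal, pericyte and meninges genes (7.69%, exact adjusted p = 0.0146) and erythroid genes (9.09%, 0.0330) passed as lower. Erythroid genes also did with a window of 500 bp (18.2%, exact adjusted p = 0.0225).

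Of 5 lists of unrelated tissues, 4 had lower shares than other genes. The exact tests gave lower shares for liver (3 of 14, adjusted p = 0.0136), heart (3 of 13, 0.0337), skeletal muscle (1 of 12, 0.00179) and germline genes (1 of 12, 0.00179), and keratinocyte genes (3 of 12, 0.0522) did not pass. The liver share was 14.3% in either replicate alone, and the skeletal muscle gene was in replicate 2 only. The heart share was 23.1% in replicate 1 alone, which did not pass (exact adjusted p = 0.0622), and the keratinocyte share was 8.33% in either replicate alone, which did (0.00737 and 0.00668). In the replicated list heart (38.5%, exact adjusted p = 0.114) and skeletal muscle genes (33.3%, 0.0592) did not pass, nor did liver genes among regions above the median signal (14.3%, 0.0539). The germline gene Dazl (9.61) and the liver genes Apoa1 (11.6) and Foxa3 (11.4) were exceptions, and Alb, Afp, Ddx4 and Prm1 had none. Against CpG-matched lists the germline share stayed below its expected 59.2% (permutation, adjusted p = 0.001), and liver (31.3% expected, 0.738), heart (38.9%, 0.342), skeletal muscle (29.3%, 0.157), microglia (17.5%, 0.741) and, narrowly, endothelial genes (23.1% against 51.4%, 0.0544) did not pass.

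**Figure D1:**
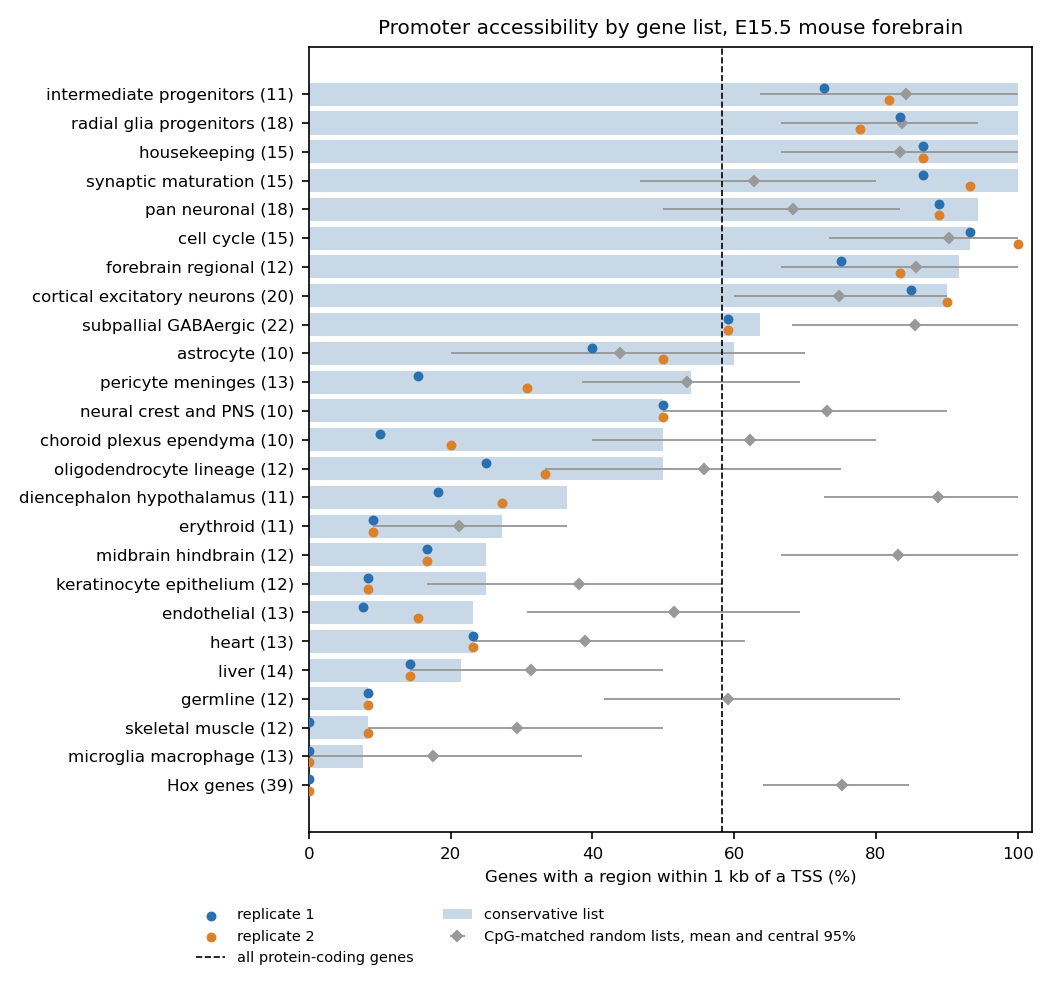
Share of genes with an accessible region within 1 kb of a TSS (x axis, percent) for 25 gene lists (y axis, number of genes in parentheses). Bars give the conservative list, points the replicates' own lists, diamonds and lines the mean and central 95% of CpG-matched random lists, and the dashed line all protein-coding genes (58.2%); the synaptic bar (100%) lies above its line and the Hox value (0%) below.

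Distal regions, those more than 1 kb from every TSS, gathered around genes of forebrain progenitors and cortical neurons. Of the 33574 conservative regions, 19605 (58.4%) were distal, and 66.4% of protein-coding genes were nearest to none. Cortical excitatory neuron genes had a median of 6 distal regions each, against a mean of 1.73 in random lists matched on the interval between neighbouring TSSs (permutation, two-sided, adjusted p = 0.005). Radial glia genes had a median of 4 against 0.910 (permutation, adjusted p = 0.005), and intermediate progenitor genes 3 against 0.385 (0.0217). In each replicate's own list the medians were 3.5, 2 and 2 for these lists.

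Sox2 had 20 distal regions (7 in replicate 1 and 12 in replicate 2), Sox9 18, the receptor phosphatase gene Ptprz1 11 and the Notch effector gene Hes1 9. Of the cortical neuron genes, the nuclear factor genes Nfib and Nfia had 19 and 13, Bcl11a, a regulator of projection neurons, 17 and Pou3f2 11. Of the intermediate progenitor genes, Insm1 had 10, Gadd45g 6 and Neurog2 4. The nuclear receptor genes Nr2f1 and Nr2f2 of the forebrain regional list had 16 and 12, and the list's median of 5.5 against 2.31 did not pass (permutation, adjusted p = 0.107). The subpallial list had a median of 2 against 0.862 (permutation, adjusted p = 0.497), with 12 at Meis2, 11 at Isl1 and 9 each at Ascl1 and Sp8. None of the other 20 lists passed in the conservative list, and the 39 Hox genes together were nearest to 1 distal region, at Hoxa1.

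Several genes without an accessible promoter still had distal regions, such as Olig3 (9), the leukocyte gene Ptprc (8), Cdh5 (7), Lmx1a (7) and Emcn (6). Subpallial genes passed in the replicated list (8.5 against 3.12, permutation adjusted p = 0.01) and within 100 kb of the TSS (0.0467), and oligodendrocyte lineage genes in the replicated list (3.5 against 0.917, 0.0225) and with every summit counted (0.0125). Without matching on the interval, forebrain regional (permutation adjusted p = 0.00167), subpallial (0.0025) and pan-neuronal genes (0.015) passed as well. The radial glia call did not pass in replicate 2 alone (permutation, adjusted p = 0.0567). The intermediate progenitor call did not pass on the replicated list (0.0510), within 100 kb of the TSS (0.0800) or with means in place of medians (0.0810). With only the regions above the median signal no list passed, and the medians of the radial glia and intermediate progenitor genes were 0.

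**Figure D2:**
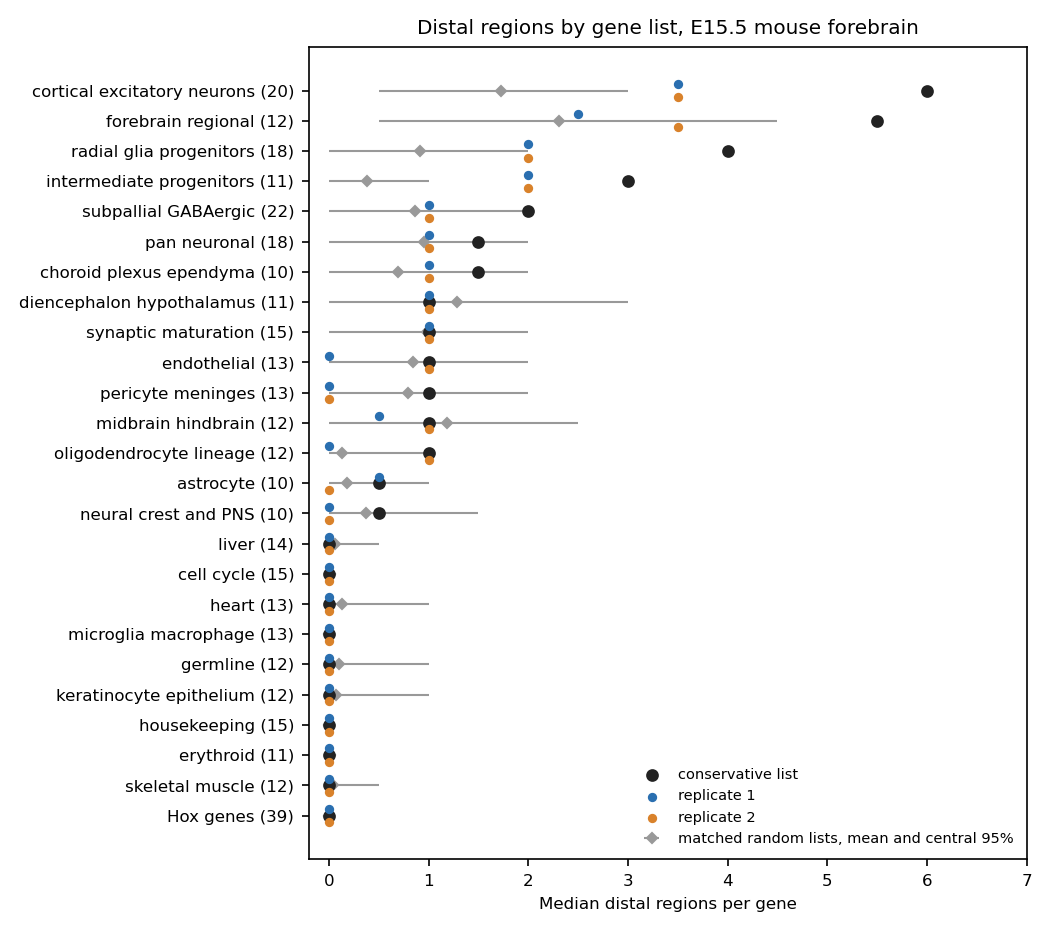
Median number of distal regions per gene (x axis) for 25 gene lists (y axis, number of genes in parentheses). Black points give the conservative list, coloured points the replicates' own lists, and grey diamonds and lines the mean and central 95% of random lists matched on the interval between TSSs; cortical excitatory neurons (6), radial glia (4) and intermediate progenitors (3) lie to the right of their lines.

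The strongest distal region of Sox2 spanned 3:34411217-34412386 (signal 9.22), 239 kb from the nearest Sox2 TSS and inside an intron of the noncoding gene Sox2ot. The 100 bp around its summit, 3:34411640-34411739, read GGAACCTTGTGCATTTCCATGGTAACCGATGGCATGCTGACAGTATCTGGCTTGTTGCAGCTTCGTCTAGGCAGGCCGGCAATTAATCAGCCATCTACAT and held the MEIS site TGACAG at 3:34411677-34411682. Insm1 had its strongest at 2:146290425-146291564 (10.3), 69.2 kb away in an intron of Ralgapa2, where 2:146291027-146291126 read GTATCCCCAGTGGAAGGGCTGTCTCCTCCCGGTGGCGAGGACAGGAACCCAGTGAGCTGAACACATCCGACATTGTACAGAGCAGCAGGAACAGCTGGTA, with the E-box CAGCTG at 2:146291118-146291123. For Nfib it was 4:82512733-82513708 (11.5), 7.43 kb upstream of the 5'-most protein-coding TSS of the gene. That region's summit lay outside exons, within the annotated spans of Nfib and of the antisense gene Gm11266. Its summit window 4:82513151-82513250 read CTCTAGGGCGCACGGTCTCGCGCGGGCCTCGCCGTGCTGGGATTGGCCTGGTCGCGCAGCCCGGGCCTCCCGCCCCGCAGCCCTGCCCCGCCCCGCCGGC and held an SP/KLF site.

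Intergenic regions led at the other genes whose strongest distal sequence was read. The Nr2f1 region, 13:78937292-78938537 (11), lay 738 kb from the gene, and 13:78937774-78937873 read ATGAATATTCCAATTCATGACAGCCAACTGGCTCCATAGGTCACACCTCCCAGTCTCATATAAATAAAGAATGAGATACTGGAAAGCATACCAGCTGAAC, with the T-box site TCACACCT at 13:78937814-78937821, a MEIS site and a CAGCTG E-box. The Meis2 region, 2:116200808-116202216 (6.63), lay 136 kb away, and 2:116201384-116201483 read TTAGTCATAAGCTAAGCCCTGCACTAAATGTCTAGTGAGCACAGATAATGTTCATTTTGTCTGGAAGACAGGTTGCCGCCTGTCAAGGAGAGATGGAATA, with a MEIS site. The region assigned to Celf4 was 18:26753258-26754426 (12.7), 999.6 kb away, and 18:26753733-26753832 read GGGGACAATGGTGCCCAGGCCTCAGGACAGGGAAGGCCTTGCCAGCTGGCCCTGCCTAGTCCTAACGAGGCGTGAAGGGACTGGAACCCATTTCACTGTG, with a CAGCTG E-box and a SOX site. The nearest TSS is a position, not a measured target.

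**Figure D3:**
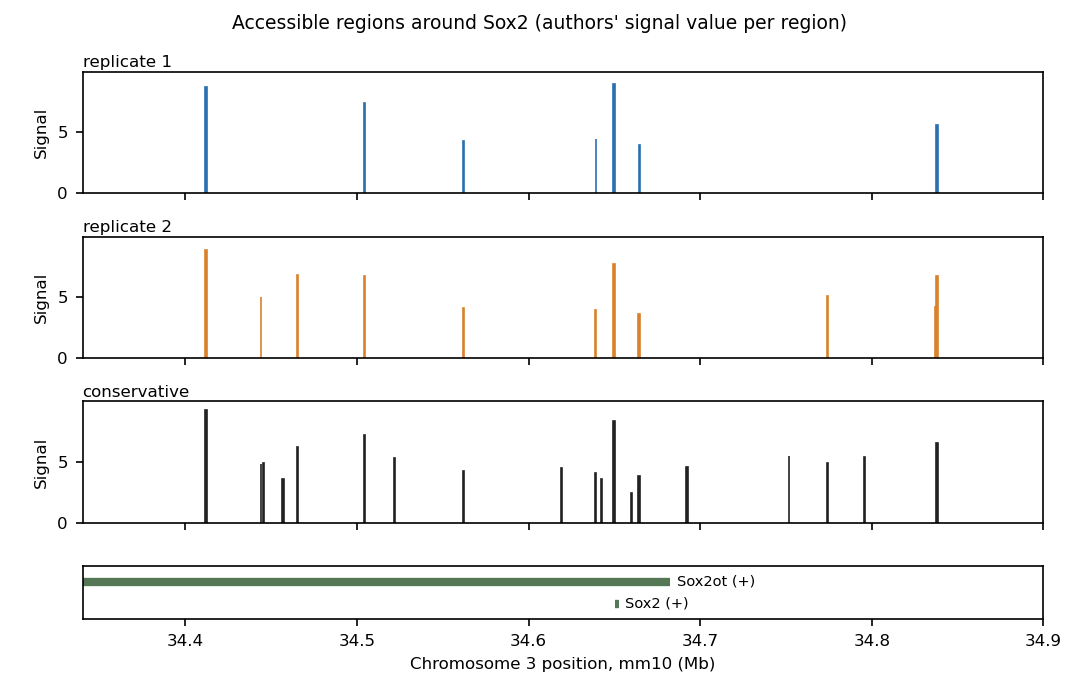
Accessible regions on chromosome 3 from 34.34 to 34.9 Mb (x axis, mm10) with their signal (y axis, the authors' value) in replicate 1 (7 regions), replicate 2 (11 regions) and the conservative list (19 regions), above the genes Sox2ot and Sox2. The Sox2 promoter region and the distal region 239 kb away appear in all 3.

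Across all protein-coding genes, Celf4, an RNA-binding protein gene of neurons, was nearest to the most distal regions, 35 (22 in replicate 1 and 25 in replicate 2). It was followed by Zfp608 (27), Pik3c3 (26), Mms22l (25) and Tenm4 (25), and then by the synaptic scaffold gene Dlg2 (24), Auts2 (24), the neuronal transcription factor gene Myt1l (23), and the cell adhesion genes Lsamp (23) and Cntnap2 (21). Sox4, Sox2, Pbx1, Kif16b and Pde4d had 20 each, and Sox11 had 18. These are raw counts, not matched on the interval between neighbouring TSSs, and genes in wide intervals can collect more regions.

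Many of the strongest distal regions matched sequence elsewhere. The highest signals lay near Pak3 (X:143482936-143483180, 55.9), Abcb11 (2:69355469-69355735, 54.4), G6pd2 (5:60042756-60043140, 42.0), Frmd4a (2:3964425-3964690, 37.7) and Gm5426 (10:96077546-96077951, 37.4), with Galc (29.0), Nxph1 (26.5), Cldn34d (25.3), 1810024B03Rik (24) and Zfp960 (23.9) next. Of these 10 regions, 5 matched the mitochondrial genome in sequence and 7 had a near-identical copy elsewhere, against 0% and 1.2% of 500 random distal regions. The 5 are among the 7, and the search for copies included the mitochondrial genome. The 10 were also narrow, with a median width of 396 bp against 821 bp.

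Dense clusters, of at least 5 distal regions at most 10 kb apart, numbered 22. The largest was near Irf2bpl, 12:86786156-86837055, with 9 regions over 50.9 kb, and 6 regions each lay in clusters near Trim27, Mpdz, Rhbg, Celf4, Nepro and Thnsl1. The clusters near Trim27 (13:21160661-21172988) and Olfr1423 (19:12005356-12012611) covered 9 and 7 tRNA genes. Replicate 1 alone gave 2 clusters and replicate 2 alone 1, while joining distances of 5 and 20 kb gave 4 and 121 and the replicated list 1105, so their number is a property of the list used.

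Promoters held more summits than any other part of the genome relative to its length. In the replicates' own lists 58.5 ± 2.43% of summits lay within 1 kb of a TSS (SD, n = 2), which is 13.4 ± 0.555 times the share of the genome. Introns held 20.1 ± 1.31% and intergenic sequence 19.4 ± 1.01%. In the conservative list the promoter share was 47.1% (10.8 times the genome's 4.37%), with 26.2% in introns, 24.4% in intergenic sequence and 2.40% in exons. The share depended on stringency: it was 30.2% in the replicated list.

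Some motifs of neural transcription factors were enriched at distal summits and others were not. Of 30 consensus motifs, 12 were more frequent in the 100 bp around the 48202 distal summits than in flanks of the same summits (exact McNemar test, Benjamini-Hochberg over motifs). In the conservative list 80.5% of regions held several summits, so summits are not independent and the p-values of the motif tests may be too small. The E-box CAGATG, bound by proneural factors such as NEUROG and NEUROD proteins, was present at 11.7% of distal summits against 7.95% of flanks (ratio 1.47, exact adjusted p = 1.325e-85), and CAGCTG, bound by ASCL factors among others, at 9.79% against 5.52% (1.77, 3.429e-136). The nuclear factor I site TTGGCA stood at 9.20% against 6.32% (1.46, 1.629e-62), the MEIS site at 10.4% against 7.62% (1.36, 4.992e-50), the full SOX site at 4.53% against 3.73% (1.21, 1.865e-09), and the POU octamer at 1.22% (1.44, 2.256e-08).

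The largest ratios belonged to CTCF, the insulator protein (1.93%, ratio 5.17, exact adjusted p = 2.068e-122), and to RFX factors, which control cilia genes (0.687%, 4.53, 1.246e-39). Across the replicates the ratios were 6.22 ± 1.51 for CTCF, 4.61 ± 0.424 for RFX, 1.5 ± 0.0757 for CAGATG, 1.82 ± 0.0948 for CAGCTG and 1.60 ± 0.0206 for nuclear factor I (SD, n = 2). Depleted were the POU MORE site (ratio 0.653, exact adjusted p = 2.629e-12) and the ROR site (0.471, 6.820e-04), both bound by factors with neural members, and the GATA (0.640, 3.523e-11), PU.1 (0.551, 0.0272) and HNF4 sites (0.594, 0.0242). The SOX site ACAAWG (0.974), the T-box site (0.912) and the MEF2 site (0.959) did not pass. The POU MORE ratio turned to 2.59 over shuffled sequence, and ROR did not pass in replicate 1 alone (0.704, exact adjusted p = 0.477). Depletion of PU.1 and HNF4 did not pass in either replicate alone (exact adjusted p in replicate 1 and replicate 2 of 1 and 1 for PU.1, 0.775 and 0.668 for HNF4). The CRE site was enriched at distal summits (1.91), with a ratio of 4.39 in replicate 1 alone and 1.44 in replicate 2 alone, which did not pass (exact adjusted p = 0.162). The homeodomain site TAATTA was not enriched over flanks (0.934, 0.0662), but was over shuffled sequence (3.18), in a wider window of 200 bp (1.12) and at the strongest summit of each region (1.23). Enrichment of NF-Y and REST sites at distal summits turned to ratios of 0.850 and 0.844 over shuffled sequence, and REST did not pass among regions above the median signal (1.42, exact adjusted p = 0.0553).

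Of the 10 motifs enriched at promoter summits, 7 were also enriched at distal summits, and ETS, NRF1 and YY1 were not. At the 42835 promoter summits the ETS site had the highest ratio (3.98, exact adjusted p = 5.541e-24), and NF-Y (7.22% against 3.66%, ratio 1.97, 6.335e-117) and SP/KLF sites (5.28% against 3.04%, 1.74, 7.171e-60) were with CAGCTG and MEIS the most frequent of the enriched motifs. RFX (3.08), CTCF (3.06), CRE (2.68), NRF1 (2.59) and YY1 (1.44) followed. The CTCF ratio was 1.87 in replicate 2 alone. YY1 did not pass in replicate 2 alone (ratio 1.35, exact adjusted p = 0.0799) or in the replicated list (1.36, 0.0957). The small MEIS enrichment (1.07) passed in the replicated list (exact adjusted p = 0.00494), but not in replicate 1 alone (0.408), in replicate 2 alone (0.117) or in a 200 bp window (0.471). TAATTA was depleted at promoters (0.425), as was CAGATG (0.901). The CAGATG depletion did not pass in the replicated list (0.962, exact adjusted p = 0.185). Over shuffled sequence both ratios rose above 1 (1.51 and 1.07), and CAGCTG (1.24) turned to 0.956.

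Set directly against promoter summits (Fisher's exact test, two-sided, Benjamini-Hochberg over 30 motifs), distal summits had 19 motifs more often. TAATTA was 5.44 times as frequent, CTCF 5.41, CAGATG 2.53, the nuclear factor I site TTGGCA 2.51 and the full SOX site 1.90. ETS (0.0717), YY1 (0.0684), NRF1 (0.101), SP/KLF (0.172), CRE (0.259) and NF-Y (0.556) were less frequent. Distal summits had a mean GC content of 51.9% and promoter summits of 62.7%. With GC content matched, 14 motifs stayed more frequent at distal summits, with CTCF at 5.51, TAATTA at 2.08, CAGCTG at 1.89 and CAGATG at 1.76, and the GATA ratio of 1.78 turned to 0.975.

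**Figure D4:**
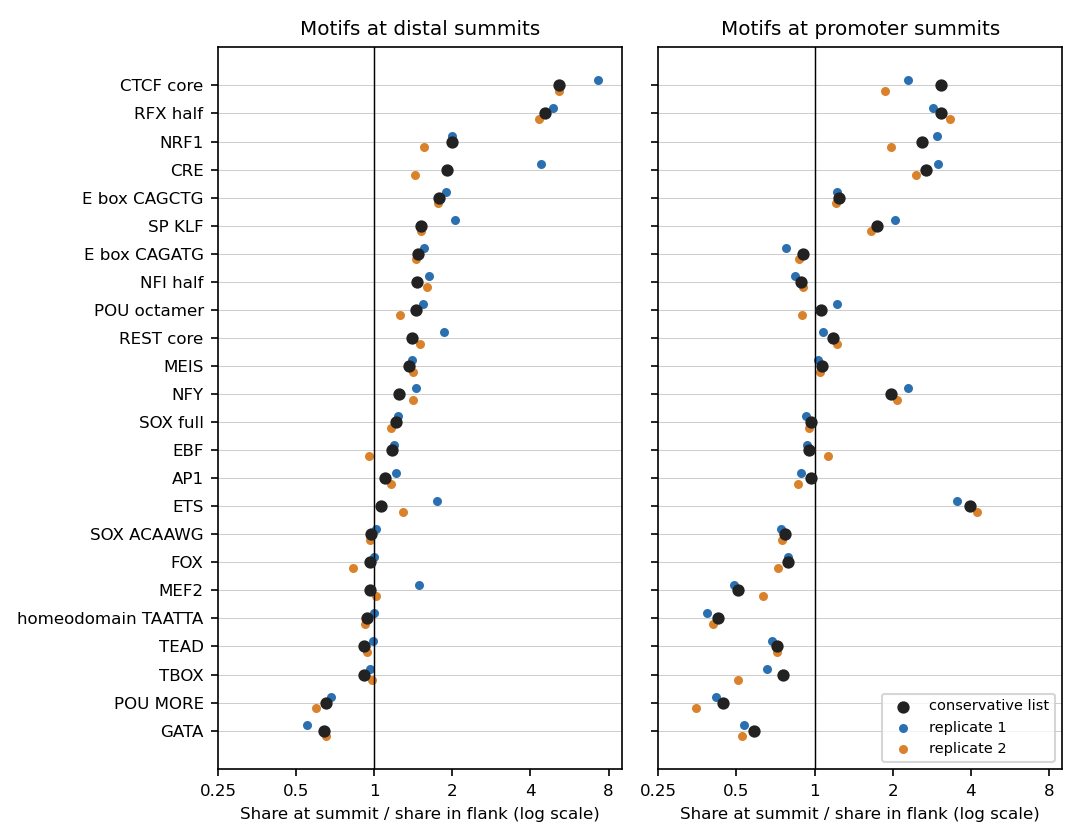
Share of summits with a motif divided by the share of flanks of the same summits (x axis, log scale) at distal summits (left) and promoter summits (right), for 24 motifs (y axis). Black points give the conservative list and coloured points the replicates; CTCF (5.17 and 3.06) and RFX (4.53 and 3.08) lie to the right of 1 in both panels, the E-box CAGATG only at distal summits (1.47 and 0.901).

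The replicates shared most regions. A region of the other replicate's list overlapped 87.3% of replicate 1's regions and 79.3% of replicate 2's, against at most 2.13% and 1.94% over 100 random shifts of the regions (permutation, one-sided, p = 0.0099 for each, the smallest that 100 shifts can give). Sharing depended on signal: in 5 equal groups from the weakest to the strongest it went through 67.2%, 78.8%, 92.1%, 98.6% and 99.9% in replicate 1 and through 55.5%, 64.5%, 82.0%, 95.1% and 99.5% in replicate 2. Over 19112 regions paired between the lists, log2 signal correlated with a Spearman rho of 0.902 and a Pearson r of 0.911. This is a correlation across regions, which are not independent replicates.

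Regions of a replicate with no counterpart even in the other's full ranked list were few, 126 (0.562%) in replicate 1 and 308 (1.25%) in replicate 2. Few lay at promoters: 15.1% and 10.4% had their strongest summit within 1 kb of a TSS, against 52.7% and 49.5% of all regions. Most of these specific regions were weak, with a median signal percentile within their own list of 10.4 in replicate 1 and 18.0 in replicate 2. In replicate 2 the strongest lay near Tmem167 (13:90325197-90326052, signal 10.3, the 78.5th percentile of its list) and Epha7, an ephrin receptor gene (4:30267766-30268467, 9.10). In replicate 1 they lay near Fam204a (19:60310650-60310909, 7.62) and 1700020N15Rik (X:69666272-69666882, 7.62). Requiring no region within 500 bp left 72 in replicate 1.

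**Figure D5:**
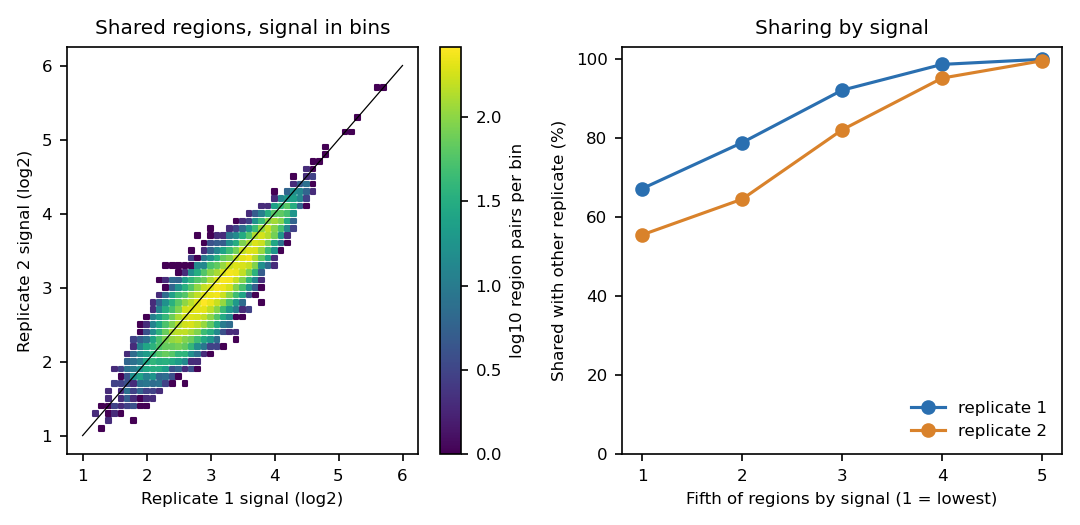
Left, log2 signal of paired regions in replicate 1 (x axis) and replicate 2 (y axis), with the colour giving the log10 number of pairs per bin and the line equality (Spearman rho 0.902). Right, share of each replicate's regions found in the other's list (y axis, percent) in 5 equal groups by signal (x axis), from 67.2% and 55.5% in the weakest to 99.9% and 99.5% in the strongest.

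The X chromosome had fewer accessible regions per Mb than any autosome. It carried 4.05 regions per Mb in replicate 1 and 4.18 in replicate 2, against 9.08 and 9.99 on the autosomes together, a ratio of 0.446 and 0.418. Among autosomes the values ran from 7.28 and 7.94 on chromosome 14 to 11.4 and 12.6 on chromosome 11. Protein-coding genes were also sparser on X, at 0.671 times the autosomal density, and 46.8% of its sequence was repeat-masked against 33.5%. X-linked genes with accessible promoters included Zic3 (8.92), Arx (9.52), Syn1 (12.7), Hprt (14.3) and Pgk1 (13.2). The Y chromosome had 12 conservative regions.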

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

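The tests of X against autosomes per gene and of −log10 p at matched signal were chosen only after the results they bear on were seen, and the read depth test was added after the other X results but before its own values. The reason given below for setting the dose bound aside was also stated only after its result. The design has 1 group, and no biological explanation was tested for the left-out or the strongest distal regions; for X, gene number and dose were.

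A signal appeared in data that the report's comparisons do not use. In the ranked list, 249 summits reached the score of 540 that the conservative list requires and were nevertheless missing from that list. Of the 70 such regions on assembled chromosomes, the highest −log10 p was 11846.2, at 1:24611587-24616167, whose nearest gene is Col19a1 (singled out after its value was seen). That region matched the mitochondrial genome over 4581 bp, and was the only one of the 70 that did (1.43%), so mitochondrial sequence does not account for the group. A near-identical copy elsewhere in the genome was found for 41.4% of the 70, against 1.2% of random distal regions. The search for copies included the mitochondrial genome, and the region near Col19a1 is part of this share. The share lies between the bounds set for and against copies as the cause, so copies may bear on part of the group. Another 41 regions had neither. The labels say that the IDR-thresholded lists were filtered with a further submitters' file, and that step may by itself account for the absence of these summits. The file was not used here, so what the filter selected for stays open.

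The strongest distal regions of the conservative list often matched other sequence. Of the 10, 5 matched the mitochondrial genome, those near Abcb11 (129 bp at 100% identity), G6pd2 (345 bp at 97.7%), Gm5426 (352 bp at 97.4%), Galc (365 bp at 99.7%) and Nxph1 (310 bp at 95.5%), and 7 had a near-identical copy elsewhere, these 5 and those near Pak3 and Zfp960. The search for copies included the mitochondrial genome, so for these 5 the copy may be the mitochondrial sequence itself, and the counts of 5 and 7 are not separate. Neither count reached the 8 set for a cause of the whole pattern or fell to the 2 set against it. Mitochondrial reads may account for the 5, and reads placed at copies, mitochondrial or nuclear, for up to 7 of the regions. The regions near Frmd4a, Cldn34d and 1810024B03Rik had neither property, and what sets their signal stays open.

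The X chromosome had fewer accessible regions per Mb than the autosomes. Fewer genes do not account for all of it, since X had 0.573 times the autosomal number of regions per protein-coding gene (0.665 and 0.624 in replicates 1 and 2, where its 0.698 regions per gene in replicate 1 lay just below the lowest autosome, 0.701), nor does masked repeat sequence, since the ratio per unmasked Mb was 0.480. In each replicate's pseudoreplicated list, 94.8% of CpG-rich genes on X had a promoter region. On autosomes 97.2% had one in replicate 1 and 97.6% in replicate 2. In these lists, CpG-rich promoters on X had 1.06 and 1.07 times the autosomal signal in replicates 1 and 2. Both ratios lay above the bound of 0.95 set against a lower accessible dose. That bound does not decide, because the sources used here do not define the background of the signal. An enrichment over a local background stays the same when dose lowers both. The pools mixed both sexes and the dose of X was not measured. How much of the lower number of regions on X a lower dose explains therefore stays open. At matched signal, −log10 p on X was 0.860 and 0.837 times the autosomal value, inside the range of single autosomes (0.823 to 1.19 and 0.817 to 1.17), so it does not set X apart. How far lower read depth on X accounts for its fewer regions stays open too. The test took the strongest 20% of distal regions by signal, on the premise that depth matters least there. That premise was not checked, since the background of the signal is not defined. The ratio per unmasked Mb in them was 0.634 in replicate 1 and 0.562 in replicate 2, against 0.408 and 0.364 over all distal regions. The first lies between the bounds of 0.6 and 0.8.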

How the results depend on the processing

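Counting every summit in place of regions, taking the strongest summit per region, and means in place of medians were chosen after seeing the data; the other alternatives were planned. The number of enriched motifs at distal summits, of motifs that differ between distal and promoter summits, and of regions specific to replicate 2 stayed within 1.5 times under every alternative run. Single results kept direction and side of the threshold in 110 of 175 alternatives for promoter lists, 144 of 200 for distal lists, 154 of 210 for distal motifs, 155 of 210 for promoter motifs and 50 of 60 for distal against promoter. In another 14, 42, 19, 10 and 2 the direction turned without passing on either side. The cause was not tested for the changes below. Depth is unknown, so how far it limits the weak regions cannot be told.

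Replicate 1's shared regions went from 87.3% to 73.3% with summits within 100 bp. On the pseudoreplicated lists the correlation went from 0.902 to 0.874 and the X to autosome ratio, as the mean of both replicates, to 0.336. Regions specific to replicate 1 fell in number from 126 to 72 with none allowed within 500 bp. The promoter share of summits, 47.1%, was 30.2% in the replicated list, 62.6% above the median signal, 40.0% with the strongest summit per region, 36.8% and 51.9% with windows of 500 and 2500 bp, and 56.8% to 60.2% in the replicates' own lists. Matching on CpG took the promoter lists called from 15 to 7 and put subpallial genes, at 63.6%, below their background. Above the median signal, forebrain regional (33.3%), intermediate progenitor (27.3%), cortical neuron (40.0%) and pan-neuronal genes (44.4%) lay below other genes. The count of distal lists called, 3, was 0 above the median signal, where radial glia and intermediate progenitor medians were 0, and 6 with no matching. The 22 clusters became 4 and 121 with joining distances of 5 and 20 kb, 1105 in the replicated list, and 1 to 2 in the replicates' own lists.

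At distal summits TAATTA, whose ratio of 0.934 had not passed, was enriched in a 200 bp window (1.12), over shuffled sequence (3.18) and at the strongest summit (1.23). Over shuffled sequence, the ratio turned at distal summits for SOX ACAAWG (1.29), POU MORE (2.59), MEF2 (3), NF-Y (0.850), REST (0.844) and FOX (2.04). At promoter summits, where the enriched motifs went from 10 to 18, it turned for CAGATG (1.07), CAGCTG (0.956), TAATTA (1.51), SOX ACAAWG (1.3), full SOX (1.46), POU MORE (1.98), MEF2 (2.13), TEAD (1.03) and FOX (1.84). MEF2 at promoters also turned with the strongest summit (1.14), and GATA, distal against promoter, with matched GC (0.975). No paired analysis was possible because there is 1 group.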

Other observations

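Gene families, some with members in the fixed lists, differed widely in promoter accessibility. These families were chosen after the data were examined and were not tested. Of 1134 olfactory receptor genes 5 had a conservative promoter region (0.441%, and 0.176% in replicate 1), and of 331 vomeronasal receptor genes 1 did. Among all genes of similar CpG ratio the shares were also low, 6.90% and 5.89%. Clustered protocadherin genes, which give single neurons their surface identity, had 4 of 57 (7.02%), against 63.9% of all genes of similar CpG ratio. Forkhead factor genes (20 of 44, 45.5% against 78.9%) and Wnt ligand genes (8 of 19, 42.1% against 74.0%, but 15.8% in replicate 1 and 26.3% in replicate 2) also lay below genes of similar CpG ratio. GABA-A receptor subunit genes lay above (11 of 12, 91.7% against 49.2%), as did ZFP genes (334 of 394, 84.8% against 67.6%). Genes of ephrins and Eph receptors, which guide axons, had 20 of 22 (90.9% against 84.0%) and a mean of 4.32 distal regions each, and SOX factor genes 14 of 19 (73.7%, below 83.4%) with a mean of 6.11. The mean over all genes was 0.897, and the families were not matched on the interval between TSSs. All 78 mitochondrial ribosomal protein genes, 38 of 40 proteasome genes and 88 of 98 ribosomal protein genes had a promoter region. Genes of similar CpG ratio had high shares too, 87.9%, 84.5% and 81.7%.

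Transfer RNA genes, read by RNA polymerase III, were often accessible. Of 403 nuclear tRNA genes, 176 (43.7%) overlapped a conservative region, 36.5% in replicate 1 and 36.0% in replicate 2, against at most 3.47% at 100 sets of shifted positions. They account for 81 of the distal regions, since tRNA genes were not among the TSSs used. Of noncoding genes away from protein-coding TSSs, 10.8% of 5419 lincRNA genes, 11% of 1946 antisense genes, 4.69% of 1939 miRNA genes and 1.48% of 9760 processed pseudogenes had a region at their TSS. In replicates 1 and 2 alone the shares were 7.36% and 8.05%, 6.99% and 7.61%, 3.09% and 3.66%, and 0.871% and 1.06%. Motif content varied with signal. From the weakest to the strongest 20% of distal summits, the share with a CTCF site went from 0.166% to 3.80%, with an RFX site from 0.0934% to 1.55%, with CAGATG from 7.81% to 15.2%, with the nuclear factor I site TTGGCA from 6% to 12.8%, and with TAATTA from 2.11% to 4.61%.

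Whether motifs divide progenitor from neuron genes was tested as a hypothesis. The full SOX site was present at 15 of 242 distal summits nearest radial glia genes (6.2%) and at 12 of 336 nearest cortical excitatory neuron genes (3.57%), which did not pass (Fisher's exact test, two-sided, p = 0.163). The E-box CAGATG was present at 7.02% and 8.93% (exact p = 0.444), both below the 11.7% of all distal summits. Both shares went in the direction the hypothesis states, and neither difference exceeded chance in these libraries.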
